A study of Mus musculus with 9 samples.

How the data were processed

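The series measured RNA from hair follicle bulge stem cells of C57BL/6J mice, sorted by flow cytometry on the surface antigens CD34 and integrin alpha6. Per the labels' protocols, individually housed mice were fed either without limit (ad libitum, AL) or each day with 70% of the food eaten by matched AL mice (dietary restriction, DR). Cells were pooled from 3 mice per group, total RNA was treated against DNA, and TruSeq RNA v2 libraries were sequenced as single reads of 51 cycles. The labels name 5 AL and 4 DR samples and give no age, irradiation state, sex, hair cycle stage, time of sampling or batch. They do not say whether each sample came from its own pool of mice, so the p-values measure the spread between these samples, which may be partly technical.

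The deposited files hold whole-number read counts per gene symbol, 1 file per sample, with no normalization applied by the authors. Per the submitters' processing notes the tools were FastQC 0.11.5, TopHat2 2.1.0, Bowtie and HTSeq 0.11.2 with the mm9 build; the annotation, the strand setting and the multiple-mapping rule are not given in the sources used here. Each file has 35012 lines, of which 6 name no gene. Those 6 lines held 25.9% to 30.7% of each library's reads and were left out of library sizes and tests, which left 35006 gene symbols, 24056 of them with a count in some library. Since the kit does not mark strand, a gene and an overlapping antisense gene share reads, and members of families such as Serpina3, and Glul with its pseudogene Glns-ps1, can exchange reads. The tables list 5 of the 13 mitochondrial protein genes at 0 in all libraries, so the mitochondrial genome is only partly represented. Gene symbols of the fixed lists were matched with a RefSeq table of the GRCm38.p6 assembly, used for names only: 9 symbols were found under an older name and 6 were not in the tables. No coordinates are given because the reference at hand is of another build.

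Library totals over genes ran from 26119459 to 33559312 counts. The 16 pairs of libraries within a group differed by far more than counting noise (chi-square per degree of freedom 24.6 to 110), so no library was a copy of another and each counted once.

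The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, a negative binomial quasi-likelihood fit on diet alone, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors (SE) of log2 fold changes are those implied by the F statistic. Levels are CPM (counts scaled to a fixed library total) after TMM, given as mean ± SD. Gene lists were tested with camera of limma 3.58.1 at its preset correlation, two-sided and adjusted over the lists, and again with an estimated correlation and with fry. In all, 48 lists were fixed, 12 of them markers of other cells; 1 of these (erythroid cells) had too few tested members for a set test. Exact two-sided permutation tests over the 126 splits of 9 libraries into 5 and 4 compared 7 library measures. Those were the gene total, genes detected, the share of the 10 most abundant genes, and the mitochondrial, no-feature, ambiguous and non-unique shares.

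The groups, tests, lists, named genes and most alternatives were chosen before the data were examined. The text names, first, up to 12 genes in each direction with the largest fold change among those past the threshold, with a mean log2 CPM of at least 2 and every DR library on 1 side of the AL mean. Symbols without a descriptive name, mitochondrial and Y-linked genes and Xist were skipped there. Second come up to 4 members with the smallest p of each list past its test and of 7 lists always reported. Last come 18 genes of stem cell identity, cell cycle and diet response, whatever their result. A few genes that the rule selects are not reported here. Other genes mentioned as list members or in the closing part were chosen after their values were seen.

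Counts were simulated for the 15447 tested genes, with a small share of them changed by a known fold. The same test recovered 22% of genes changed 1.5-fold and 75% of those changed 2-fold, and 6.36% of its calls were unchanged genes. In the data 40.7% of genes passed, so the adjustment was less strict there, and these rates do not measure recovery in the real comparison. Small changes can still be missed at this number of libraries. Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, library size only, no filter and a stricter filter, the DESeq2 Wald test, limma-voom with and without library quality weights, robust dispersion, a replicate block, 1 surrogate variable (sva 3.50.0), other thresholds, and leaving out each library.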

Results

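RNA of CD34+ alpha6+ hair follicle bulge stem cells was compared between 5 libraries from ad libitum fed mice (AL) and 4 libraries from mice on 70% of that food intake (DR). The bulge holds the long-lived stem cells that regrow the hair at each cycle and that form part of the niche of melanocyte stem cells. The title of the series places the comparison in a study of hair graying and of stem cell quiescence under dietary restriction. Libraries held 26119459 to 33559312 gene counts, and a mean of 20263 genes was detected. Neither this depth (exact permutation p = 0.548) nor any of the other 6 library measures passed adjustment. The smallest exact p was 0.0238, for the share of ambiguous reads (adjusted p = 0.167). The share of mitochondrial counts was 2.17% ± 0.460 in AL and 1.52% ± 0.324 in DR (SD, n = 5 and 4; exact permutation p = 0.0714, adjusted p = 0.167).

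Bulge cells of DR mice had lower transcript levels of the cell division machinery, of cholesterol synthesis and of several matrix proteins, and higher levels of genes known to respond to glucocorticoids. Of 15447 genes tested, 6290 (40.7%) differed by edgeR's quasi-likelihood test, 2941 higher and 3349 lower in DR. A change of at least 2-fold was found for 617 higher and 1156 lower genes, and of at least 4-fold for 131 and 362. In 32.9% of the tested genes the libraries of the diets did not overlap, where chance alone gives 1.59%. The first principal component held 59.1% of the variance and parted the diets. Of the fixed gene lists, 14 passed camera at its preset correlation, 7 higher and 7 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.38, and 55 of 100 splits of the libraries gave at least as many lists. Counting the real split, a median as large came from 16 of 100 for quiescence, 12 for p53 targets and 12 for the clock. It came from 8 for hemidesmosomes and 7 for fibroblasts, so chance is not excluded for these lists. The other called lists had 1 to 3 such splits. Judged by the camera p, a value as small came from 14 of 100 splits for G2 and M phase and 16 for cholesterol synthesis. It came from 28 for G1, 31 for S phase, 32 for autophagy and 35 for the respiratory chain. For mTORC1, the glucocorticoid response and insulin it came from 1, 2 and 6. The camera p-values below therefore do not measure chance among these libraries. With library quality weights or on ranks 7 of the 14 did not pass, those of quiescence, hemidesmosomes, G1, insulin, mTORC1, p53 targets and fibroblasts. Each list below is given with its member counts, which rest on the test of single genes. Members can vary together (estimated correlation 0.83 for G2 and M phase and 0.65 for S phase), so such counts are not independent findings. Those counts are to be read against the 40.7% of all tested genes that passed. A list near that share, such as those of quiescence, p53 targets and the clock, has no clear excess of calls.

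Among the largest rises were Fkbp5 and Tsc22d3, textbook targets of the glucocorticoid receptor. Fkbp5, a co-chaperone of that receptor, rose from 16.4 ± 5.84 CPM in AL to 438 ± 29.97 CPM in DR (SD, n = 5 and 4; log2 fold change 4.74, SE 0.27, edgeR adjusted p = 1.8e-06). Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose from 40.4 ± 12.3 to 649 ± 63.4 CPM (4.0, SE 0.22, adjusted p = 1.7e-06). Pdk4, the kinase that holds back pyruvate oxidation in fasting, rose by a log2 fold change of 4.49 (SE 0.16, adjusted p = 8.2e-08). Of the 22 tested members of the glucocorticoid response list, 15 rose and none fell (17 and 0 when adjusted over the list alone), with a median log2 fold change of 1.29 (camera adjusted p = 1.8e-16; adjusted p = 0.38 with an estimated correlation). Klf15 (3.12), Zbtb16 (2.41), Ddit4 (2.18) and Klf9 (1.45) were among those that rose. Per1, also a member, had a log2 fold change of 0.49 that did not pass (adjusted p = 0.059), but did without AL replicate 4 (0.024) or AL replicate 5 (0.048). On all libraries it passed by the DESeq2 Wald test (adjusted p = 0.028) and in limma-voom with quality weights (0.028). In edgeR it passed with 1 surrogate variable (0.028) or with library size only (0.049).

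The other largest rises included Glul, the glutamine synthetase (28.2 ± 4.0 to 598 ± 127 CPM, log2 fold change 4.40, SE 0.17), whose pseudogene Glns-ps1 (4.43) can take its reads. Dpep1, a membrane dipeptidase, rose by 5.15 (SE 0.29), the organic anion transporter gene Slc10a6 by 4.94 (SE 0.36), Best2 by 4.52 (SE 0.33) and the proteoglycan gene Spock2 by 3.87 (SE 0.17). The protease inhibitor genes Serpina3k (8.46, SE 0.54), Serpina3j (4.34, SE 0.61) and Serpina3n (3.94, SE 0.44) also rose; they are close copies that can exchange reads, so their single values are uncertain. Serpina3k stood at 0.0496 ± 0.040 CPM in AL, so its fold rests on very few AL reads.

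Genes of cell division fell together. Mki67, the proliferation marker Ki-67, was at 164.5 ± 92.7 CPM in AL and 10.2 ± 3.93 CPM in DR (SD, n = 5 and 4; log2 fold change -4.01, SE 0.53, edgeR adjusted p = 2.7e-04). Of 43 tested G2 and M phase genes, 40 fell and none rose (42 and 0 adjusted over the list alone), with a median log2 fold change of -3.56 (camera adjusted p = 1.7e-19; adjusted p = 0.68 with an estimated correlation). Ect2 (-3.95), Ube2c (-4.31) and Nuf2 (-4.91) were those with the smallest p. The kinetochore and spindle genes Kntc1 (-5.50, SE 0.76), Bub1 (-5.08, SE 0.75) and Troap (-5.48, SE 0.80), and Pbk (-5.14), Melk (-4.80), Mxd3 (-4.93) and Fam64a (-5.48), were among the 12 largest falls. Without DR replicate 2 the folds of Kntc1 and Troap moved to -6.37 and -6.34. Of 40 S phase genes, 25 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 1.9e-07; adjusted p = 0.77 with an estimated correlation). Uhrf1 (-3.92), Pola1 (-1.43) and Cdca7 (-1.18) were examples. The AL libraries were not alike here. The mean log2 CPM of the G2 and M phase list was 2.72 in AL replicate 5, against 4.37 to 5.18 in the other AL libraries and 0.67 to 1.78 in DR.

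Regulators of the G1 phase moved in the same direction: of 22 tested cyclins, kinases and inhibitors, 12 fell and 2 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.77 with an estimated correlation). Cyclin D1 (Ccnd1) fell from 102 ± 15.6 to 31.9 ± 4.67 CPM (log2 fold change -1.68, SE 0.14, edgeR adjusted p = 1.6e-05), Cdk4 by 1.13 and E2f1 by 3.33 on the log2 scale, while the pocket protein gene Rbl2 rose by 1.19. The list's call was lost without AL replicate 4 (camera adjusted p = 0.063) or without DR replicates 1 and 2 (0.10). Leaving out AL replicate 1 as well as those 2 DR libraries also lost it (0.066). The inhibitors Cdkn1a (0.72, adjusted p = 0.092), Cdkn1b (0.16, adjusted p = 0.15) and Cdkn1c (0.86, adjusted p = 0.065) did not pass the main test. On all libraries Cdkn1a and Cdkn1c did pass by the DESeq2 Wald test (adjusted p 0.045 and 0.027). They also passed in limma-voom with quality weights (0.023 and 0.027) and in edgeR with 1 surrogate variable (0.0077 and 0.015). Cdkn1a passed without AL replicate 5 (adjusted p = 0.031), and Cdkn1c without AL replicate 4, AL replicate 5 or DR replicate 2 (adjusted p 0.031 to 0.047).

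**Figure D1:**
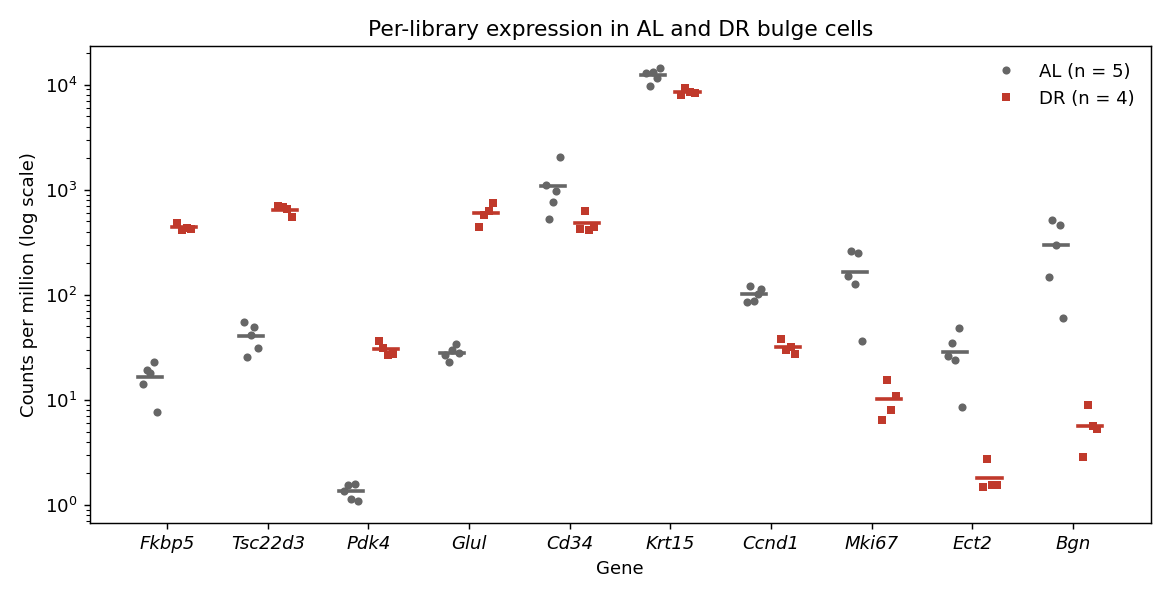
CPM on a log scale for 10 named genes in each AL library (grey circles, n = 5) and each DR library (red squares, n = 4); horizontal lines are group means. Fkbp5, Tsc22d3, Pdk4 and Glul lie higher in every DR library than in any AL library, and Mki67 in AL replicate 5 (36.7 CPM) lies between the other AL libraries and DR.

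Genes associated with stem cell quiescence were higher on balance: of 25 tested, 7 rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0047; adjusted p = 0.67 with an estimated correlation). The median was 0.17, and 0.28 without AL replicate 5 or 0.31 without DR replicate 2. Of 100 splits of the libraries, 16 gave a median as large, so chance is not excluded for this list. The members that rose most were Pdk4 and Txnip, an inhibitor of glucose uptake and thioredoxin (500 ± 79.0 to 4338 ± 747 CPM, log2 fold change 3.12, SE 0.17), followed by Rbl2 (1.19), Ccng2 (0.79) and Foxc1 (0.68). Sfrp1, a secreted Wnt inhibitor, fell by 1.72 (SE 0.24), and Fgf18, which keeps follicles at rest, fell by 1.6 on the log2 scale. Pdk4 also belongs to the glucocorticoid list.

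Bulge identity markers moved apart. Of 22 tested, 8 fell and 3 rose (8 and 3 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.29). Its mean log2 CPM was 9.38 to 9.66 in AL and 9.13 to 9.32 in DR, lower by exact permutation (adjusted p = 0.047) and by fry (adjusted p = 0.026). Cd34, the antigen used in the sort, was at 1083 ± 579 CPM in AL and 479 ± 102 in DR (log2 fold change -1.18, SE 0.33, edgeR adjusted p = 0.016). Without AL replicate 5 the log2 fold change of Cd34 shrank to -0.82. Its call was lost without DR replicate 3 (-1.10, adjusted p = 0.052) or without DR replicates 1 and 2 (-1.33, adjusted p = 0.054). Leaving out AL replicate 1 as well as those 2 also lost it (-1.33, adjusted p = 0.086). Itga6, the other sorting antigen, had a log2 fold change of -0.12 (SE 0.10, adjusted p = 0.34). Npnt, a basement membrane protein of the bulge, fell by 3.00 (SE 0.26), Krt5 by 0.91 and Postn by 1.10 on the log2 scale, while Runx1 (0.70), Foxc1 (0.68) and Cd200 (0.66) rose. Krt15 (-0.54, SE 0.17, adjusted p = 0.024) did not pass without AL replicate 1, DR replicate 1, DR replicate 3 or DR replicate 4 (adjusted p 0.051 to 0.069). Sox9 (-0.38, SE 0.12, adjusted p = 0.023) did not pass without DR replicate 1 (adjusted p = 0.066) or DR replicate 2 (adjusted p = 0.063). The transcription factor genes Lhx2 (-0.02, SE 0.18) and Nfatc1 (-0.10, SE 0.16) and the receptor gene Lgr5 (-0.15, SE 0.26) did not pass.

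Among signals that steer the follicle, neither the BMP list (7 rose and 2 fell of 23, counts also adjusted over the list alone; camera adjusted p = 0.28) nor the Wnt list (3 rose and 10 fell of 24, likewise; camera adjusted p = 0.26) passed. Axin2, a feedback target of Wnt signalling, rose by 1.25 (SE 0.12) and Lgr6 fell by 0.79 on the log2 scale. Without AL replicate 1 and DR replicates 1 and 2, Lgr6 did not pass (edgeR adjusted p = 0.052). Fstl1, an extracellular BMP modulator, fell by 1.52, while Atoh8 (1.21), Bmp7 (0.77) and Bmpr1b (2.66, at under 1 CPM in both groups) rose. Of 13 tested factors of the melanocyte niche, 2 rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 0.88); its median was 0.04, its mean -0.10 and the camera direction was up, and the median was below 0 with upper-quartile scaling, library size only or without DR replicate 2 (-0.08). Kitl, the stem cell factor that melanocytes need, did not pass (65.9 ± 19.9 against 62.2 ± 8.86 CPM, log2 fold change -0.08, SE 0.23, adjusted p = 0.80); without AL replicate 5, where it was lowest, its log2 fold change was -0.27 (adjusted p = 0.062). Edn2, an endothelin, fell by 2.06 (SE 0.50, adjusted p = 0.0075), Wnt10a by 0.69 and Hgf, at under 1 CPM, fell by 2.1, while Jag1 rose by 0.74 (SE 0.11). The calls of Wnt10a (edgeR adjusted p = 0.056) and Hgf (0.063) were lost without DR replicates 1 and 2. That of Wnt10a was also lost with AL replicate 1 left out as well (0.075).

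Genes of nutrient sensing also moved. Of 27 genes of insulin, IGF and FoxO signalling, 12 rose and 6 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.68 with an estimated correlation and 0.13 on ranks). Those that rose included the receptors Igf1r (47.4 ± 6.52 to 89.3 ± 10.5 CPM, log2 fold change 0.91, SE 0.12, edgeR adjusted p = 2.0e-04) and Insr (0.91), the FoxO genes Foxo3 (1.09) and Foxo1 (0.99), Sesn1 (1.5) and Bcl6 (1.56). The IGF-binding protein gene Igfbp5 fell by 4.21 (SE 0.33), from 497 ± 83.5 to 26.9 ± 11.8 CPM, and Igfbp3 fell by 2.53 on the log2 scale. Of 25 components of the mTORC1 pathway, 11 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.38 with an estimated correlation). The members with the smallest p were Tsc1 (1.19), Flcn (0.97), Eif4ebp2 (0.93) and Ddit4 (2.18); Tsc1 and Ddit4 are known as inhibitors of mTORC1 and Eif4ebp2 as a translational repressor that it inactivates. Autophagy and lysosome genes were higher on balance, with 14 risen and 3 fallen of 37, as also adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.77 with an estimated correlation). Gabarapl1 (1.06), Wipi1 (1.01) and Atg14 (0.78) rose and the protease gene Ctsz fell by 0.64 on the log2 scale.

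Cholesterol synthesis genes fell: 20 of 24 passed and none rose (21 and 0 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.9e-07; adjusted p = 0.73 with an estimated correlation). Sqle, which encodes squalene epoxidase, fell from 74.4 ± 20.2 to 30.1 ± 6.41 CPM (log2 fold change -1.31, SE 0.20), with Stard4 (-0.99) and Nsdhl (-0.96). AL replicate 5, lowest of AL for the G2 and M phase list, was also lowest of AL here. Its mean log2 CPM was 4.37, against 4.98 to 5.02 in the other AL libraries and 3.86 to 4.20 in DR. A difference in hair cycle stage between the pools is therefore not excluded for this list either. Of 77 nuclear genes of the respiratory chain, 40 fell and 2 rose, as also adjusted over the list alone, with a median of -0.26 (camera adjusted p = 7.8e-05; adjusted p = 0.78 with an estimated correlation). Ndufb2 (-0.85), Ndufs8 (-0.92), Atp5g1 (-1.13) and Atp5k (-0.83) had the smallest p.

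Of 23 clock genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.77 with an estimated correlation). Per2 rose from 14.2 ± 3.88 to 78.4 ± 33.1 CPM (log2 fold change 2.46, SE 0.27), with Hlf (0.99) and Tef (0.96), while Dbp, a clock output gene, fell by 1.26 (SE 0.33, adjusted p = 0.011). The list's call was lost without AL replicate 1 (adjusted p = 0.055) or DR replicate 4 (adjusted p = 0.068), and its median of 0.25 was 0.39 to 0.43 without AL replicate 4, AL replicate 5, DR replicate 2 or DR replicate 3. Of 28 p53 targets, 9 rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.38 with an estimated correlation). Trp53inp1 (2.25), Sesn1 (1.5) and Eda2r (1.65) rose and Trp73 fell by 1.43 on the log2 scale. The median was 0.15, and 0.07 without DR replicate 1, 0.08 without AL replicate 1 and 0.24 without DR replicate 2.

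**Figure D2:**
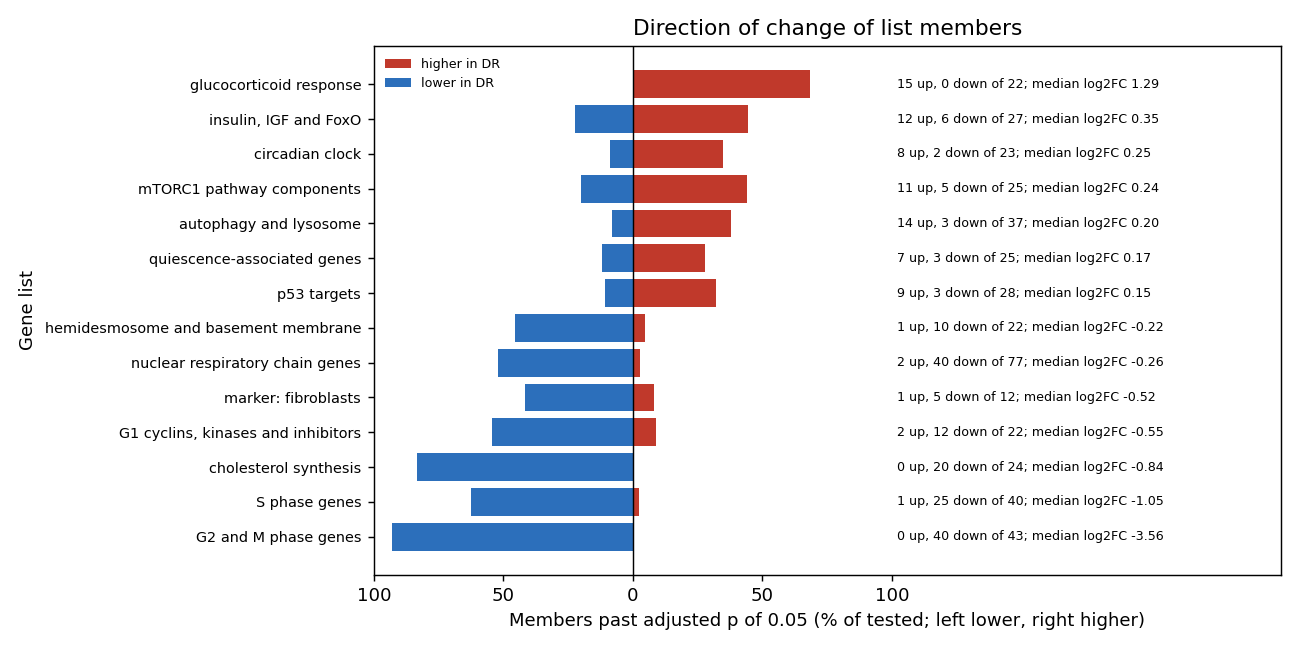
Percent of tested members that were higher (red, right) or lower (blue, left) in DR past the adjusted p threshold, for the 14 gene lists past camera at its preset correlation, with counts and the median log2 fold change printed beside each bar. The glucocorticoid response list has 15 higher and 0 lower members of 22, and the G2 and M phase list 0 higher and 40 lower of 43.

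Matrix genes were among the largest falls. Biglycan (Bgn), a small matrix proteoglycan, fell from 298 ± 197 to 5.65 ± 2.47 CPM (log2 fold change -5.71, SE 0.67, edgeR adjusted p = 1.3e-04), and the collagen gene Col14a1 from 14.6 ± 7.26 to 0.166 ± 0.107 CPM (-6.41, SE 0.59). AL replicate 5, lowest of AL for the G2 and M phase list, was also lowest of AL for Bgn (59.8 CPM, others 149 to 519) and Col14a1 (4.52 CPM, others 11.3 to 21.6). The proton pump gene Atp6v1b1 (-6.28, SE 0.77) and the peptide hormone gene Cck (-5.11, SE 0.67) complete the 12 largest falls. Hemidesmosome and basement membrane genes were lower on balance, with 10 fallen and 1 risen of 22 (10 and 2 adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.77 with an estimated correlation). Npnt, Lamb1 (-1.04), Col4a1 (-0.95) and Lamc1 (-0.47) had the smallest p, and the call was lost without AL replicate 1, AL replicate 4, AL replicate 5, DR replicate 3 or DR replicate 4 (adjusted p 0.054 to 0.21). Of 12 fibroblast markers, 5 fell and 1 rose, as also adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.59 with an estimated correlation). Col1a1 (-3.34), Thy1 (-2.17), Loxl1 (-2.06) and Col5a1 (-2.05) fell. That call was lost without AL replicate 1, AL replicate 4, DR replicate 1, DR replicate 3 or DR replicate 4 (adjusted p 0.050 to 0.16).

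Markers of other cells varied between libraries. Endothelial markers had a mean log2 CPM of 2.1 in DR replicate 1, 1.62 in DR replicate 2 and 1.5 in AL replicate 1, and of 0.83 or less in the other libraries; 1 of 13 fell and none rose, as also adjusted over the list alone (camera adjusted p = 0.66). Immune markers, 13 tested and none past the threshold, also adjusted over the list alone, were highest in the same 3 libraries (2.26, 1.86 and 1.69; camera adjusted p = 0.12), and the list passed without AL replicate 1 (adjusted p = 0.012) or DR replicate 3 (adjusted p = 0.033), and on ranks with all libraries (adjusted p = 0.024), higher in DR. Leaving out those 3 libraries, a choice made after seeing the data, gave 4601 genes. Melanocyte markers were scarce, and 4 of 10 fell, as also adjusted over the list alone (camera adjusted p = 0.29), among them Dct, from 7.24 ± 4.14 to 1.6 ± 0.483 CPM (log2 fold change -2.17, SE 0.42, adjusted p = 0.0021).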

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

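The tests of explanations below were chosen after the result was seen, except the other splits of the libraries. The scalings of lists and the fit without DR replicates 1 and 2 were also added after the data were seen, but their bounds were set before their values were known. Of 306 groups of values examined, 13 held a library far from the rest of its group, where chance gives about 1 in 20. AL replicate 5 was low for Lgr5 (315 CPM, others 674), Kitl (30.7 CPM, others 74.7), Atp6v1b1 (4.78 CPM, others 50.2) and the mean log2 CPM of the cholesterol synthesis list (4.37, others 5.0). DR replicate 1 was high for Fkbp5 (482 CPM, others 423) and low for Eif4ebp2 (47.6 CPM, others 66.2) and Cck (0.036 CPM, others 0.401). DR replicate 2 was high for Cd34 (629.9 CPM, others 428) and Ect2 (2.72 CPM, others 1.52) and low for Atoh8 (14.8 CPM, others 17.0). DR replicate 4 was low for Klf15 (135 CPM, others 185). AL replicate 1 was low for the ribosomal protein list (mean log2 CPM 5.04, others 5.40) and AL replicate 4 high for the glycolysis and hypoxia list (5.63, others 5.26). For the count of 6290 genes, 1 of 100 splits drawn from the 126 gave as many, the real one, and the highest other gave 1027. A chance split of these libraries is therefore unlikely to give that count. If samples of a group share pools, the splits do not cover chance among mice. For the count of 14 lists, 55 of 100 splits gave as many and the highest other gave 22, so chance is not excluded for that number.

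For the fall of cell cycle genes, 1 of 100 splits gave a median of the G2 and M phase list as large as 3.56, the highest other being 3.06. By the list mean the exact permutation p over all 126 splits was 0.016, where 0.0079 is the smallest possible. The split that puts AL replicate 5 with the DR libraries, not among the 100, gave a larger difference in that mean. The tables argue against scaling as the cause, since the median stayed at -3.54 or lower under 3 other scalings. For hair matrix cells in the AL libraries, a median log2 fold change of -1 or lower was asked of 8 matrix and hair shaft markers. These stood at 1 to 20 CPM in AL, and their median was 0.024 (95% bootstrap interval over genes -0.25 to 1.31). That of the whole marker list was 0.0009 to 0.14 without 1 library. The markers thus did not fall together. Matrix cells are not excluded, because only 14 of 29 markers were tested and the bound was set after the result was seen. Markers that the sorted cells also express need not fall that far. A difference in hair cycle stage between the pools may account for the pattern and cannot be told apart from an effect of diet on division, because AL libraries ranged over 2.46 log2 units in the mean of the list and no label gives a stage. An effect of diet stays open and untested.

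The rise of glucocorticoid response genes exceeded nearly all other splits. A median as large as 1.29 came from 2 of 100, the real one included, the highest other being 1.36. By the list mean the exact permutation p over all 126 splits was 0.0079, the smallest possible (adjusted p = 0.047). That mean log2 CPM was 5.99 to 6.74 in AL and 7.71 to 8.11 in DR. Chance is therefore unlikely but not excluded. If samples of a group share pools, splits of libraries do not cover chance among mice. More stress during cell isolation in DR than in AL would raise immediate early and heat shock genes as well. The heat shock median was -0.24 (-0.28 to -0.15 without 1 library), which argues against such a difference. The immediate early median was 0.16, and 0.025 to 0.27 without 1 library. Its interval over genes of -0.06 to 0.22 leaves out the spread between libraries. Other splits gave a median of up to 0.65 in size, so the immediate early list does not decide the question. Endothelial and immune cells in DR replicates 1 and 2 are argued against too, since the median was 1.27 without them. Time of collection relative to feeding or light cannot be told apart from diet, because the labels give no time. Of 22 clock genes outside the list 10 passed the threshold. That is near the share of all tested genes that passed (40.7%), so the count does not decide the question. A response of the bulge cells to corticosterone under dietary restriction is a further hypothesis that was not tested.

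Bgn, Col14a1 and Col1a1 fell with other fibroblast-type genes. Fewer fibroblasts in the DR libraries would require the abundant fibroblast transcripts Dcn, Lum and Col3a1 in AL at a level near that of Bgn (298 CPM). None of the 3 exceeded 2.49 CPM in any AL library, which argues against that explanation. The sort on CD34 and alpha6 would also remove most fibroblasts. Pdgfra was at 1.07 ± 0.338 CPM in AL and 3.02 ± 1.85 CPM in DR, a spread that leaves it undecided. The median of the fibroblast list was -0.52, and -1.25 without AL replicate 1 and DR replicates 1 and 2. AL replicate 5 was lowest of AL for Bgn (59.8 CPM) and Col14a1 (4.52 CPM), as for the G2 and M phase list, so the difference in hair cycle stage left open there is not excluded here. Lower matrix gene expression within the sorted cells under DR may remain as a hypothesis, not tested.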

How the results depend on the processing

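The exact permutation of list means, the scalings of lists and the fits without several libraries were added after the data were seen. The number of genes stayed within 1.5 times of 6290 in every alternative except with the 2-fold limit (1773, a stricter criterion by construction). Without 1 library it ran from 5176 to 6402, and no gene called in both a fit and the main test changed direction. Higher and lower genes numbered 2463 and 3821 with upper-quartile scaling and 2275 and 3582 with library size only, against 2941 and 3349. The replicate block gave 6413 genes on 8 libraries, against 6402 on the same libraries without it. Whether replicate numbers pair the samples is not settled. Correlations of same-numbered libraries were low (0.04, 0.13, 0.23 and 0.03), and only number 3 matched best both ways. The block, which leaves out AL replicate 5, gave 16 lists, and the same 8 libraries without it gave 15. Immune markers passed with the block (adjusted p = 0.044) and not on those libraries without it (0.24). With and without the block, those libraries added ATF4 (adjusted p = 0.039 and 0.019) and DNA repair (0.0048 and 0.017) and left out hemidesmosome genes (0.18 and 0.21). Among named genes they added Cdkn1a (0.0092 and 0.031), Cdkn1c (0.025 and 0.047) and Per1 (0.0101 and 0.048) either way. With the block Kitl passed (-0.27, adjusted p = 0.037) and Krt15 did not (0.075); on those libraries without it Kitl did not pass (0.062) and Krt15 did. The hemidesmosome list did not pass with DESeq2 size factors (0.051), nor fibroblast markers with upper-quartile scaling (0.071) or library size only (0.055). The list count was 7 with quality weights, 8 on ranks, 24 with fry and 0 with an estimated correlation; the cause was not tested. Immune markers passed on ranks (0.024), and fry added the bulge, Wnt, Notch, ATF4, fatty acid oxidation, tricarboxylic acid cycle, sirtuin, DNA repair, adipocyte and hair shaft lists (0.011 to 0.045). The quiescence, hemidesmosome, G1, insulin, mTORC1, p53 and fibroblast lists did not pass with quality weights (adjusted p 0.057 to 0.15) or on ranks (0.062 to 0.19). Without 1 library the list count ran from 11 to 15. By exact permutation 16 lists passed, 11 of them among the 14 (smallest possible p 0.0079); the insulin (adjusted p = 0.14), clock (0.056) and fibroblast (0.056) lists did not. The other 5 (adjusted p = 0.047 each) were the bulge, fatty acid oxidation, sirtuin and DNA repair lists and Schwann cell markers, which were up in camera and passed in the opposite direction; the cause was not tested. Of 99 named genes tested, 90 were called. Of these, 84 kept their call in every alternative that tested them, 6 lost it in some (Cd34, Krt15, Sox9, Lgr6, Hgf, Wnt10a), and none reversed. Of the 9 others, 4 passed in some alternative (Cdkn1a, Cdkn1c, Kitl, Per1). Direction was read only where a result or its alternative passed. No library measure passed in any setting run, but none could pass alone at this number of libraries. Depth limits folds of genes under 1 CPM, such as Hgf and Bmpr1b.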

Other observations

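Genes in this paragraph were chosen after their values were seen. Prodh, which breaks proline down, rose from 19.7 ± 1.54 to 118 ± 8.71 CPM (SD, n = 5 and 4; log2 fold change 2.58, SE 0.09, edgeR adjusted p = 8.2e-08), while Pycr1 (-3.02, SE 0.18) and Aldh18a1 (-2.60, SE 0.21), which encode enzymes of proline synthesis, fell. Both belong to the ATF4 amino acid response list, of which 4 rose and 10 fell of 28 (5 and 12 adjusted over the list alone; camera adjusted p = 0.094, and 0.019 without AL replicate 5). Psat1 fell by 1.79 and Mthfd2 by 2.91 on the log2 scale, and Cth rose by 1.64. Of 33 fatty acid oxidation genes 9 rose and 5 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.15, but 0.049 without DR replicates 1 and 2, 0.011 with fry and 0.047 by exact permutation); Ucp2 fell by 1.82 on the log2 scale. Of 39 DNA repair genes 7 rose and 13 fell, as also adjusted over the list alone (camera adjusted p = 0.094; 0.017 without AL replicate 5 and 0.048 without DR replicate 2). Parp1 (-1.36) and Brca1 (-2.95) fell, and Atm (0.66) and Xpc (0.64) rose.

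Immediate early genes were abundant in both diets: Fos took 1.5% to 2.47% of gene counts per library, and its log2 fold change was 0.21 (SE 0.23, adjusted p = 0.49). Of 25 immediate early genes 2 rose and 2 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.66). Of 20 heat shock genes 1 rose and 8 fell, as also adjusted over the list alone (camera adjusted p = 0.31), and of 81 ribosomal protein genes 1 rose and 7 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.29). Xist was at 1467 ± 386 CPM in AL and 624 ± 108 CPM in DR (log2 fold change -1.23, SE 0.20, adjusted p = 8.4e-04), and 4 Y-linked genes together had 2 counts over the 9 libraries.

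No other list passed camera at its preset correlation with all libraries. Of 32 ribosome biogenesis genes 8 fell and 0 rose (camera adjusted p = 0.16), of 23 tricarboxylic acid cycle genes 9 fell and 2 rose (0.30), of 15 mitochondrial genome transcripts 6 fell and 0 rose (0.26), of 11 Notch genes 3 rose and 0 fell (0.26), and of 12 sirtuin and NAD genes 1 rose and 3 fell (0.37). Fatty acid synthesis genes were 6 higher and 6 lower of 22 (0.51), and glycolysis and hypoxia targets 5 higher and 10 lower of 27 (0.51), with a median of -0.35 (-0.23 without DR replicate 2) and a mean of -0.09. The median and the camera direction differed in sign for translation factors (median 0.03, down), inflammatory and secreted factors (-0.06, up), Schwann cell markers (-0.27, up) and sebaceous gland markers (0.14, down); their camera adjusted p ran from 0.88 to 0.95. These medians are not firm: without 1 library they ran from 0.0011 to 0.092 for translation factors, from -0.13 (AL replicate 5) to 0.14 (AL replicate 4) for inflammatory and secreted factors, from -0.40 (DR replicate 1) to -0.12 (AL replicate 4) for Schwann cell markers and from -0.01 (AL replicate 5) to 0.22 (AL replicate 2) for sebaceous gland markers. That of translation factors was below 0 with upper-quartile scaling (-0.03) or library size only (-0.04).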
